A study of Mus musculus with 20 samples.

How the data were processed

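RNA sequencing of mouse hypothalamus gave 20 libraries in 5 groups, young control (4), acute control (5), acute Gly-Low (4), old control (4) and old Gly-Low (3). Per the labels' protocols, the libraries were non-directional and made from poly-A RNA, so reads of a gene and of a gene on the other strand cannot be told apart. The deposited values are raw read counts per gene, whole numbers with no normalization. The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0 with build GRCm38, without saying how each was used, and the annotation release and the strand setting of the counting are not given in the sources used here. The table held 54532 genes, of which 54495 matched the GENCODE annotation of GRCm38 used here for symbols, positions and lengths; the other 37 held at most 0.0198% of the counts of any library. There were 21380 genes with no count in any library and 0 duplicated columns among the libraries. Total counts ran from 15848372 to 27399753 per library.

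Genes with low counts were removed with filterByExpr by group, libraries were scaled with TMM, and each comparison was tested with edgeR 4.0.16 by its quasi-likelihood F test in R 4.3.3, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05 with no minimum fold. The acute diet contrast was fitted on its 9 libraries. The age and old diet contrasts were fitted on the 11 libraries of the ageing arm. The contrast between the young groups and the test of a different diet effect in the arms were fitted on all 20 libraries. Log2 fold changes are given with their standard errors, and CPM as the mean with its SD over libraries. Adjusted p-values of genes are from edgeR unless another tool is named.

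The groups, tests, samples, alternatives, 55 gene lists (29 of pathways and 26 of cell types) and the rule for named genes were fixed before the data were examined. The rule takes the 8 protein-coding genes with the smallest p in each direction among those past the threshold, all of them where fewer pass, and the 3 with the smallest p where fewer than 3 pass. It adds 12 genes of feeding, glycation and glia whatever their values, and up to 4 members with the smallest p of each list whose test passes. For some lists of the old diet comparison no members are named, a choice made after the values were seen. For the difference between arms the rule takes the 5 genes with the smallest p, and 1 of them is not reported here. Lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over the lists of a comparison, and beside it with an estimated correlation and with fry. As fry tests whether the genes of a list move one way on balance and compares them with no other genes, its counts answer another question than those of camera. A list p is the adjusted p at the preset correlation.

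The 7 measures per library were compared between groups with two-sided exact permutation tests and adjusted over 21 tests. The length slope of a library is the slope of its log2 CPM deviation from the mean of all libraries on log2 transcript length. As the old controls enter both the age and the old diet contrast, 100 simulations with no age and no diet effect gave the shares and covariance that shared controls then produce. The old controls were also split 2 and 2.

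Alternatives were DESeq2 1.42.0, its size factors or upper-quartile factors in edgeR, no filter, a filter of CPM 1 in 3 libraries, limma-voom with quality weights, other sets of samples in the fit, the replicate number as a block, 1 surrogate variable (sva 3.50.0) and leaving out each library in turn. Alternatives chosen after seeing the data were an offset from the trend of each library over 40 length bins, the length slope as a covariate in a fit on all 5 groups, the fit without acute controls 2, 3 and 5, which hold pituitary transcripts, and the fit without young control 2 and old control 3, which have the lowest length slopes of the ageing arm. The length measure was changed from merged exon length to the median length of basic transcripts after the first results, because merged lengths of some genes such as Glo1 were inflated, and the results with either are given.

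Libraries of old control and old Gly-Low with the same replicate number deviated together from their group means, with correlations from 0.448 to 0.639 over 3 pairs, although 0 of 3 old Gly-Low libraries correlated best with the old control of its own number. The pairing by number enters the fits only as the alternative with the replicate number as a block. The pairing comes from the titles, and the column names carry other numbers for old Gly-Low.

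The steps were tested on simulated counts with 200 changed genes drawn from the means and sizes of the real libraries. For the acute diet, 64.6% of genes with a 2-fold and 92.0% with a 4-fold change were recovered over 16841 genes, with 3.70% false calls. For age, 15% and 65.0% were recovered over 17880 genes with 6.98% false calls, and for the old diet 13% and 65.0% over 17882 genes with 6.02% false calls. A planted length trend alone gave 2950 calls over 16913 genes without the offset and 5 with it, and 76.4% of changed genes were recovered with the offset. The planted trend was linear, equal in all libraries of the changed group and smaller in size than the real slope difference of −0.66 between the acute groups. These counts therefore do not show what the real trend gives or how fully the offset removes it.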

Results

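Gene expression was measured by RNA sequencing in the hypothalamus of male C57BL/6J mice from 5 groups, 20 libraries in all. Gly-Low is a diet with compounds added to lower glycation, the non-enzymatic attachment of reactive sugar products such as methylglyoxal to proteins. The ageing arm held 4 young control libraries (3 months old, control diet for 1 week), 4 old control libraries (25 months old, control diet for 5 months) and 3 old Gly-Low libraries (25 months old, Gly-Low for 5 months). The acute arm held 5 acute control and 4 acute Gly-Low libraries, all at 4 months of age after 1 week of diet. Total counts ran from 15848372 to 27399753 per library. The labels do not state whether each library came from a separate animal, so the p-values measure the spread between samples. Coordinates are from GRCm38.

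The acute Gly-Low libraries differed from the acute controls in their make-up. Transcripts of the mitochondrial genome took 20.9% ± 2.73 (SD, n = 4) of the counts in acute Gly-Low and 6.98% ± 1.46 (SD, n = 5) in acute control. Cytosolic ribosomal protein transcripts took 6.41% ± 1.40 and 2.03% ± 0.186 of the counts in the same groups. The 10 most abundant genes held 21.6% ± 2.68 of the counts in acute Gly-Low and 9.51% ± 2.06 in acute control. The length slope, the change in log2 CPM deviation per doubling of transcript length, was −0.42 ± 0.12 in acute Gly-Low and 0.23 ± 0.05 in acute control, which means that short transcripts had a larger part of the acute Gly-Low libraries. For each of these 4 measures the acute groups did not overlap, with p = 0.0159 by a two-sided exact permutation test, the smallest p possible, and p = 0.0833 after adjustment over the 21 tests of this family. In the ageing arm the mitochondrial share was 12.4% ± 4.81 in young control (n = 4), 9.03% ± 4.61 in old control (n = 4) and 6.14% ± 1.21 in old Gly-Low (n = 3), with p = 0.371 for age and p = 0.343 for diet by the exact permutation test. The smallest p possible is 0.0286 for age and 0.0571 for the old diet, which therefore could not pass. This test is unpaired. In the 3 pairs of an old control and an old Gly-Low library with the same title number, the mitochondrial share was 6.69% and 4.94%, 8.14% and 6.12%, and 15.8% and 7.36%. The length slope was 0.20 and 0.35, 0.06 and 0.12, and −0.27 and 0.23. In each pair the share was lower and the slope higher in old Gly-Low. The column names carry other numbers for old Gly-Low, so these pairs may not belong together. No paired test of these measures was run, so a paired diet effect is neither shown nor excluded. Old control 3 and young control 2 had the highest shares of their groups, 15.8% and 17.2%, and the lowest length slopes, −0.27 and −0.34. Young control 2 lies within the range of the acute Gly-Low libraries in these 2 measures.

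**Figure D1:**
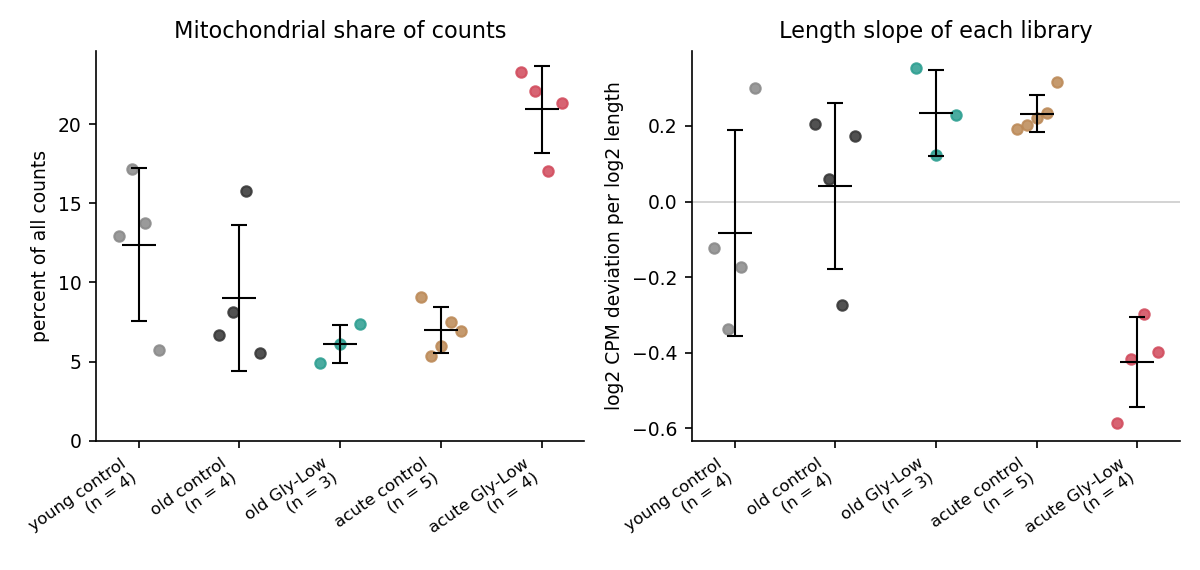
Percent of all counts from the mitochondrial genome (left) and length slope in log2 CPM deviation per log2 length (right), with 1 dot per library and a bar for the mean ± SD. The 4 acute Gly-Low libraries lie between 17.0% and 23.3% on the left, and the 5 acute control libraries between 5.35% and 9.11%.

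The acute comparison asks what 1 week of the diet changes in the hypothalamus of young mice. Agrp (ENSMUSG00000005705, chromosome 8, 105566698 to 105637393), which encodes the agouti-related peptide of hunger-promoting arcuate neurons, rose from 9.21 ± 1.76 CPM (SD, n = 5) to 50.4 ± 19.2 CPM (SD, n = 4), a log2 fold change of 2.47 ± 0.25 (SE) with an adjusted p of 1.33e-06. Ghsr (ENSMUSG00000051136, chromosome 3, 27371351 to 27378010), the ghrelin receptor, fell from 10.3 ± 0.961 CPM to 5.29 ± 3.02 CPM, a log2 fold change of −0.94 ± 0.28 with an adjusted p of 0.0105. Pomc (ENSMUSG00000020660, chromosome 12, 3954951 to 3960642), the precursor of melanocortin peptides, fell from 856 ± 1300 CPM to 40.3 ± 20.8 CPM, by −4.37 ± 0.96 on the log2 scale (adjusted p = 0.00126), and the acute controls with high Pomc also held pituitary transcripts. Without acute control 2, which had 3161 CPM, the log2 fold change of Pomc was −2.77 (adjusted p = 0.000761), and without acute Gly-Low 3 that of Ghsr was −1.42 (adjusted p = 8.36e-05). Pmch, the precursor of melanin-concentrating hormone, rose from 192 ± 84.7 CPM to 633 ± 112 CPM, a log2 fold change of 1.74 ± 0.27 (adjusted p = 6.4e-05). Glo1 (ENSMUSG00000024026, chromosome 17, 30584936 to 30626871), which detoxifies methylglyoxal, rose from 145 ± 27.1 CPM to 266 ± 14.0 CPM, a log2 fold change of 0.89 ± 0.14 (adjusted p = 9.13e-05).

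Of the other feeding genes, Mc4r passed and Npy did not. Mc4r, a melanocortin receptor, had a log2 fold change of −0.72 ± 0.27 and passed the test with an adjusted p of 0.0317. Npy, the orexigenic partner of Agrp, had 12.3 ± 3.15 CPM in acute control and 18.0 ± 12 CPM in acute Gly-Low and did not pass the test (0.57 ± 0.39, adjusted p = 0.218). Cartpt (0.13 ± 0.19, adjusted p = 0.574), Hcrt (−0.26 ± 0.38, adjusted p = 0.578), Lepr (−0.30 ± 0.24, adjusted p = 0.301), Ghrl (−0.73 ± 0.84, adjusted p = 0.471) and the astrocyte gene Gfap (0.47 ± 0.26, adjusted p = 0.142) did not pass either. With a per-library transcript-length offset, Npy was −1.10 (adjusted p = 0.0269; range over the alternatives 0.0174 to 0.789) and Cartpt was −0.85 (adjusted p = 0.00175; range 0.0013 to 0.984). With that offset the log2 fold changes of Pmch and Glo1 were 0.39 (adjusted p = 0.22) and −0.09 (adjusted p = 0.62), and the call of Ghsr was lost (−0.39, adjusted p = 0.231; range over the alternatives 8.36e-05 to 0.298), while that of Agrp was kept under every alternative (1.02 to 2.68). Mc4r lost its call without acute control 1 (adjusted p = 0.077), acute control 5 (0.062), acute Gly-Low 2 (0.078), acute Gly-Low 3 (0.062) or acute Gly-Low 4 (0.058), and Npy passed without acute Gly-Low 2 (0.89, adjusted p = 0.0199). The annotation places 7 other genes over the Agrp locus, 5 of them on the other strand, 1 over Pmch and 2 over Glo1, so these counts may hold reads of a neighbour.

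**Figure D2:**
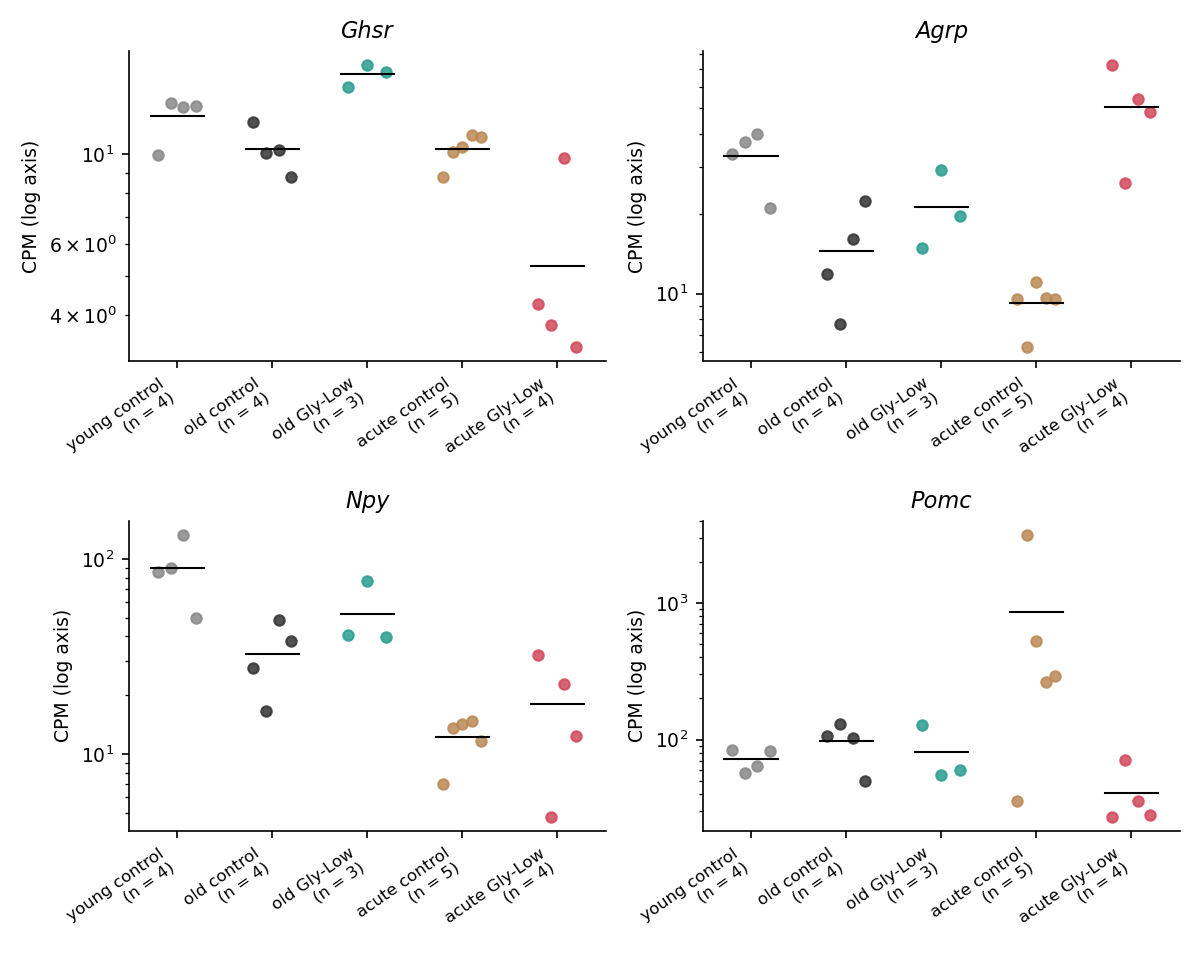
CPM on a log axis of Ghsr, Agrp, Npy and Pomc in every library, with 1 dot per library and a line at each group mean. Agrp has a mean of 9.21 CPM in acute control and 50.4 CPM in acute Gly-Low, and Pomc spreads from 35.5 to 3161 CPM within the acute controls.

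Across the genome 10005 of 17161 genes tested differed in the acute comparison, 4774 higher and 5231 lower in acute Gly-Low. Among the genes with the smallest p that rose were Rbm3, a cold-inducible RNA-binding protein, from 70.0 ± 7.0 to 312 ± 16.8 CPM (2.17 ± 0.12, adjusted p = 1.22e-07), the glutathione transferase Mgst1 (2.46 ± 0.13), Commd3 (1.83 ± 0.11), Rida (2.43 ± 0.16), Tceal8 (2.17 ± 0.14), Chmp5 (1.70 ± 0.11) and the mitochondrial ribosome genes Mrpl41 (1.92 ± 0.12) and Mrpl27 (1.89 ± 0.13). Among those that fell were Snrnp200, a spliceosome helicase, from 192 ± 21.0 to 35.1 ± 2.91 CPM (−2.43 ± 0.13, adjusted p = 1.22e-07), Pcdhgc4 (−2.81 ± 0.16), Ptpro (−2.16 ± 0.13), Abhd2 (−1.95 ± 0.12), Adgrf5 (−2.67 ± 0.16), the calcium pump Atp2b3 (−2.84 ± 0.18), Aqr (−2.01 ± 0.12) and the histone demethylase Kdm5b (−1.95 ± 0.12). The adjusted p of these 16 genes ran from 1.22e-07 to 1.88e-07.

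Transcripts of the translation and respiration machinery rose as groups, beside the higher mitochondrial and ribosomal protein shares of the acute Gly-Low libraries. Of 79 cytosolic ribosomal proteins, 77 rose and 0 fell, over all genes and adjusted over the list alone. Rps29 was at 2.76 ± 0.21 and Rpl37a at 2.29 ± 0.17. The list mean was 2.11 (adjusted p = 2.04e-25 by camera, and 0.608 with an estimated correlation). With the transcript-length offset that mean was 0.83, against a median of −0.05 over all genes tested. Of 75 genes of nuclear-encoded oxidative phosphorylation, 68 rose by either adjustment. Ndufb3 was at 2.15 ± 0.15 and Ndufc2 at 2.21 ± 0.15. The mean was 1.53 (adjusted p = 2.01e-19 by camera, and 0.608 with an estimated correlation), and with that offset the mean was 0.39. All 13 mitochondrially encoded proteins rose by either adjustment. mt-Nd4l was at 2.79 ± 0.28 and mt-Cytb at 1.94 ± 0.20. Their mean was 2.26 (adjusted p = 3.76e-06; adjusted p = 0.608 with an estimated correlation), and it was −0.45 with the length slope as a covariate in a fit on all 5 groups.

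Lists of border macrophages, meninges, erythrocytes and glucocorticoid targets also ranked higher. Of 13 border macrophage and leukocyte genes, 10 rose over all genes and adjusted over the list alone. F13a1 (2.11 ± 0.27) and Lyve1 (2.65 ± 0.43) were among them, with a list p of 0.00799 (adjusted p = 0.608 with an estimated correlation). Of 13 genes of meninges and fibroblasts, 9 rose over all genes and 10 adjusted over the list alone. Crabp2 (3.23 ± 0.33) and Igfbp2 (1.51 ± 0.24) were among them, with a list p of 0.0177 (adjusted p = 0.643 with an estimated correlation). All 7 erythrocyte genes rose by either adjustment, among them Hbb-bs (2.16 ± 0.37) and Hbb-bt (2.11 ± 0.37), near-identical globin copies that could share reads. Their list p was 0.0177 (adjusted p = 0.608 with an estimated correlation), and with the transcript-length offset the list mean was 0.58. Of 16 genes of the glucocorticoid response, 7 rose and 1 fell by either adjustment. Tsc22d3 was at 1.58 ± 0.16 and Sult1a1 at 2.30 ± 0.28 (adjusted p = 0.0227 by camera; adjusted p = 0.643 with an estimated correlation).

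Lists of immediate early genes, leptin and insulin signalling, energy balance receptors, glycolysis and the ventromedial nucleus ranked lower. Of 20 immediate early genes, which mark recent neuronal activity, 14 fell and 0 rose over all genes and adjusted over the list alone. Nptx2 (−2.17 ± 0.24) and Fos (−2.15 ± 0.40) were among them, with a list p of 0.0177 (adjusted p = 0.643 with an estimated correlation). Acute control 1 had raw counts of 202 for Fos, 13 for Fosb and 41 for Egr1. The acute Gly-Low libraries had 62 to 166, 3 to 15 and 79 to 148. For these genes the lower level in acute Gly-Low thus rests on acute controls 2 to 5. Nptx2 had 293 counts in acute control 1, against 50 to 124 in acute Gly-Low. Of 22 genes of leptin and insulin signalling, 12 fell and 1 rose by either adjustment. Grb10 was at −1.61 ± 0.13 and Stat3 at −1.88 ± 0.16. Its list p was 0.00885 (adjusted p = 0.608 with an estimated correlation), and the list mean of −0.79 became 0.40 with the length slope as a covariate in that fit on all 5 groups. Of 26 energy balance receptors, 16 fell and 3 rose by either adjustment. Insr was at −1.45 ± 0.17, Calcr at −1.73 ± 0.24, Ntsr1 at −2.59 ± 0.34 (0.20 with that covariate) and Ramp1, which rose, at 1.80 ± 0.17 (list p = 0.0227; adjusted p = 0.608 with an estimated correlation). Of 20 glycolysis genes, 14 fell and 3 rose over all genes, 14 and 4 adjusted over the list alone. Pfkp was at −1.40 ± 0.12 and Pfkl at −1.67 ± 0.17 (0.12 with that covariate); the list p was 0.0135 (adjusted p = 0.635 with an estimated correlation). Of 10 markers of the ventromedial nucleus, 6 fell by either adjustment, such as Fezf1 (−1.24 ± 0.18), with a list p of 0.0363 (adjusted p = 0.608 with an estimated correlation), and the call was lost without acute control 1 (adjusted p = 0.06) or acute control 4 (adjusted p = 0.065). Members of other neuronal lists, which did not pass by camera, also fell. Among 14 general neuron markers 9 fell and 1 rose (mean −0.71). Among 10 GABAergic markers 6 fell and 0 rose (mean −0.83), and among 12 striatum markers 9 fell and 1 rose (mean −0.69). Fewer moved among 10 glutamatergic markers, where 3 fell, and in the suprachiasmatic nucleus 3 rose and 3 fell. The fall was thus not particular to the ventromedial nucleus.

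The direction of change followed transcript length. With genes parted into 5 bins of equal number by transcript length, in the shortest bin (56 to 1334 bases), 61.5% rose and 4.17% fell. In the longest bin (from 4220.5 bases), 6.97% rose and 60.8% fell. Spearman's rho between log2 fold change and transcript length was −0.56 across genes, which are not independent replicates. A fit on all 5 groups gave 8913 acute genes with a median log2 fold change of −0.08. With the length slope of each library as a covariate in that fit 3325 genes passed, 1791 of them shared with the 10005 in the same direction, and the median was 0.15. In total 12 of 55 fixed lists passed, 7 higher and 5 lower, and 0 did with an estimated correlation (camera), and 7 with the transcript-length offset. By fry, which tests a list against no change and not against other genes, 32 passed.

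**Figure D3:**
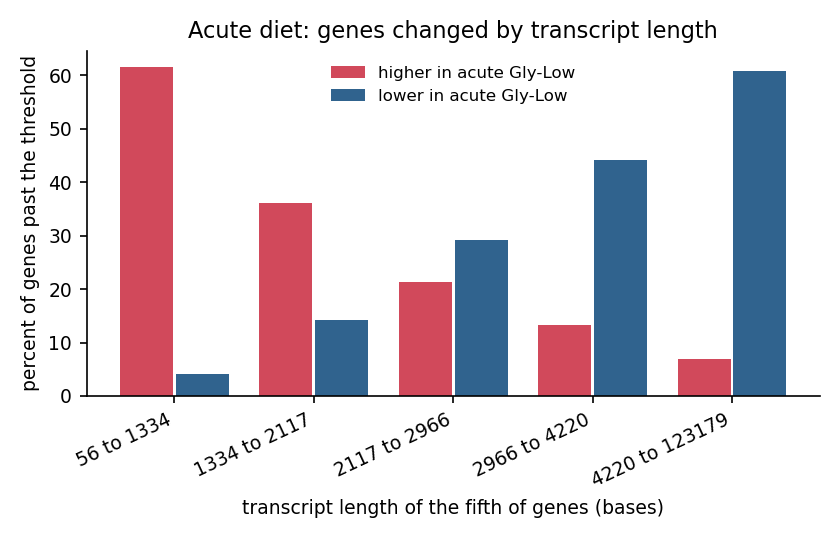
Percent of the genes in each of 5 bins of transcript length (bases, horizontal axis) that passed the threshold as higher or lower in acute Gly-Low. The percent that rose goes from 61.5 in the shortest bin to 6.97 in the longest, and the percent that fell from 4.17 to 60.8.

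The age comparison asks what differs between old and young mice on the control diet. Immune genes of microglia and antigen presentation were higher in the old controls. Mpeg1 (ENSMUSG00000046805, chromosome 19, 12460779 to 12465283), a perforin-like protein of macrophages, rose from 29.1 ± 4.83 CPM (SD, n = 4) to 103 ± 14.7 CPM (SD, n = 4), a log2 fold change of 1.81 ± 0.18 (SE) with an adjusted p of 0.0103. H2-K1 (chromosome 17, 33996017 to 34000347), a class I histocompatibility gene, rose from 43.4 ± 4.14 to 88.2 ± 5.27 CPM (1.00 ± 0.12, adjusted p = 0.0307), and its relative H2-Q6 from 0.655 ± 0.286 to 5.20 ± 1.55 CPM (2.94 ± 0.36, adjusted p = 0.0307). Clec7a, a receptor for fungal sugars on reactive microglia, rose from 0.251 ± 0.234 to 6.75 ± 1.13 CPM (4.66 ± 0.62, adjusted p = 0.0473), and the immunoglobulin gene Ighm from 7.51 ± 1.35 to 22.9 ± 4.23 CPM (1.59 ± 0.22, adjusted p = 0.0473). Reads of H2-K1 and H2-Q6 could be split between near-identical family members.

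These 5 genes and E230025N22Rik (4.75 ± 0.66, adjusted p = 0.0473), which lies outside the naming rule and was chosen after its values were seen, were the 6 of 18281 genes that passed, all higher in old control. The genes with the smallest p among the lower ones did not pass and were Ago3 (−0.81 ± 0.14, adjusted p = 0.095), Ahsa2 (−0.97 ± 0.16, adjusted p = 0.095) and Dusp11 (−0.90 ± 0.16, adjusted p = 0.0994). None of the 12 genes of feeding, glycation and glia that were fixed beforehand passed. Agrp had 33.0 ± 8.40 CPM in young control and 14.5 ± 6.29 CPM in old control (−1.22 ± 0.34, adjusted p = 0.257), Npy had 89.5 ± 34.1 and 32.7 ± 13.7 CPM (−1.48 ± 0.38, adjusted p = 0.219), and with the acute controls as the young reference in a fit on all 5 groups their log2 fold changes were 0.66 and 1.41. The others were Ghsr (−0.29, adjusted p = 0.695), Ghrl (−0.31, adjusted p = 0.941), Pomc (0.42, adjusted p = 0.763), Cartpt (−0.37, adjusted p = 0.799), Hcrt (−1.04, adjusted p = 0.54), Pmch (−0.24, adjusted p = 0.884), Lepr (−0.20, adjusted p = 0.886), Mc4r (0.02, adjusted p = 0.986), Glo1 (0.10, adjusted p = 0.92) and Gfap (1.73 ± 0.62, adjusted p = 0.403).

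**Figure D4:**
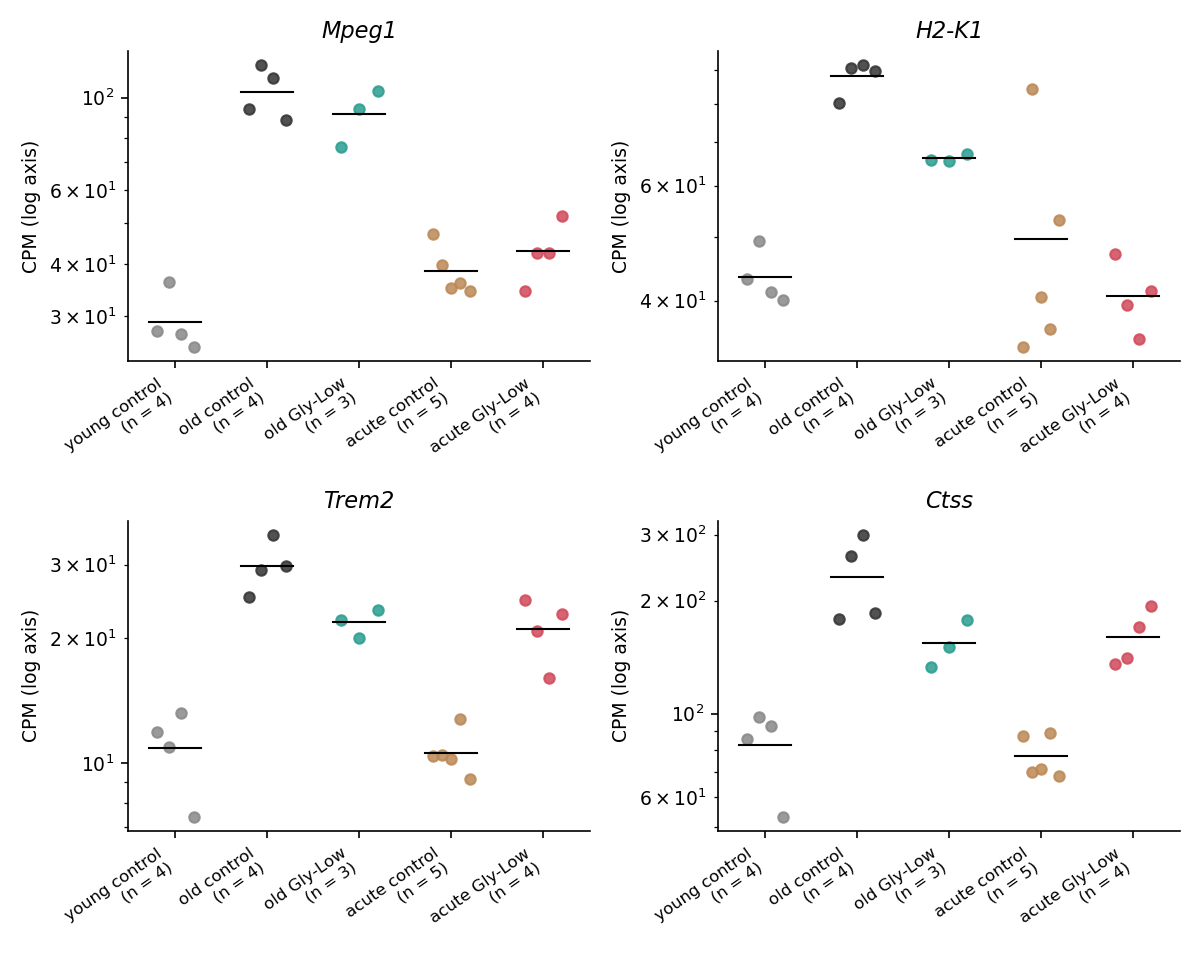
CPM on a log axis of Mpeg1, H2-K1, Trem2 and Ctss in every library, with 1 dot per library and a line at each group mean. Mean Mpeg1 is 29.1 CPM in young control and 103 CPM in old control, and mean Trem2 is 10.8 and 29.8 CPM.

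As groups, immune lists ranked higher in old control. Of 21 complement and MHC genes, 2 rose over all genes and 14 adjusted over the list alone. H2-D1 was at 1.30 ± 0.25 and H2-T23 at 0.82 ± 0.16 (list p = 3.26e-15; adjusted p = 0.0272 with an estimated correlation). Of 21 genes of disease-associated microglia, 1 rose over all genes and 14 adjusted over the list alone. Trem2 was at 1.44 ± 0.21, Lyz2 at 1.87 ± 0.32 and Lpl at 1.47 ± 0.28, which was −0.29 with the acute controls as reference in a fit on all 5 groups (list p = 3.72e-14; adjusted p = 0.0569 with an estimated correlation). Of 29 interferon response genes, 0 passed over all genes and 13 rose adjusted over the list alone. Oasl2 (1.10) and Gbp7 (1.01) were among them, with a list p of 8.82e-13 (adjusted p = 0.21 with an estimated correlation). Of 18 microglia markers, 0 passed over all genes and 6 rose adjusted over the list alone. Ctss was at 1.47 ± 0.25 and Itgam at 1.01 (list p = 1.69e-08; adjusted p = 0.0569 with an estimated correlation). Of 20 NF-kappaB and cytokine genes, 2 rose adjusted over the list alone and 0 over all genes, Ccl4 (4.76 ± 0.82) and Il1b (3.67 ± 0.81), with a list p of 0.000888 (adjusted p = 0.0569 with an estimated correlation). Of 13 border macrophage and leukocyte genes, 1 rose over all genes and 3 adjusted over the list alone, among them Ptprc (1.37 ± 0.22), with a list p of 0.0131 (adjusted p = 0.371 with an estimated correlation).

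Glial, vascular and blood markers also ranked apart with age. Of 18 markers of mature oligodendrocytes, 0 passed over all genes and 5 rose adjusted over the list alone. Mobp (0.81 ± 0.19) and Anln (0.89 ± 0.22) were among them, with a list p of 0.000939 (adjusted p = 0.371 with an estimated correlation). Of 19 reactive astrocyte genes, 4 rose and 1 fell adjusted over the list alone and 0 over all genes. Serpina3n was at 0.76 ± 0.18, and the heat shock gene Hspb1 was the one that fell (list p = 0.00501; adjusted p = 0.188 with an estimated correlation). Of 9 erythrocyte genes, 6 rose adjusted over the list alone and 0 over all genes. Alas2 was at 3.27 ± 0.62 and Hbb-bt at 3.40 ± 0.69 (list p = 3.16e-08; adjusted p = 0.21 with an estimated correlation). Of 11 mural cell markers, 4 fell adjusted over the list alone and 0 over all genes. Acta2 was at −1.79 ± 0.39 and Vtn at −1.14 ± 0.27 (list p = 0.000648; adjusted p = 0.115 with an estimated correlation). The 14 genes of meninges and fibroblasts ranked lower with none past either adjustment. Slc6a13 was at −1.37 and Slc6a20a at −1.16 (list p = 0.00276; adjusted p = 0.477 with an estimated correlation), and the list mean of −0.88 was −0.46 without young control 3.

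Peptide hormone and proteostasis lists ranked lower in old control, with 0 members past the test over all genes. Of 16 neuroendocrine hormones, 4 fell adjusted over the list alone, which were Crh (−1.62 ± 0.40), Oxt (−1.37 ± 0.34), Npvf (−1.74 ± 0.50) and Ghrh (−0.98 ± 0.29), with a list p of 0.000939 (adjusted p = 0.477 with an estimated correlation), while with the acute controls as reference in a fit on all 5 groups the list mean of −0.52 became 0.33. Of 7 orexigenic neuropeptides, 2 fell adjusted over the list alone (list p = 0.00201; adjusted p = 0.274 with an estimated correlation), with a mean of −0.69 that became 0.60 against the acute controls. Of 13 anorexigenic neuropeptides, 2 fell adjusted over the list alone (list p = 0.00662; adjusted p = 0.59 with an estimated correlation), with a mean of −0.44 that became 0.08. Of 14 heat shock genes, 2 fell adjusted over the list alone, Hspb1 (−1.66 ± 0.32) and Hsp90ab1 (−0.48), with a list p of 0.00364 (adjusted p = 0.274 with an estimated correlation). Of 19 genes of the unfolded protein response, 1 fell adjusted over the list alone. Calr was at −0.63 and Herpud1 at −0.38 (list p = 0.0131; adjusted p = 0.614 with an estimated correlation), and the mean of −0.18 became 0.04 against the acute controls. Of 21 genes of the ghrelin and growth hormone axis, 1 fell adjusted over the list alone, the mitochondrial uncoupling gene Ucp2 (−0.96 ± 0.21), with a list p of 0.018 (adjusted p = 0.162 with an estimated correlation).

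Genes of nuclear-encoded oxidative phosphorylation had a mean of −0.32 with 66 of 75 negative (list p = 0.000119; adjusted p = 0.76 with an estimated correlation), cytosolic ribosomal proteins a mean of −0.28 (list p = 0.00325; adjusted p = 0.794 with an estimated correlation) and mitochondrially encoded proteins a mean of −0.42 (list p = 0.0108; adjusted p = 0.716 with an estimated correlation). In these lists 0 members passed by either adjustment, and against the acute controls the means were 0.60, 0.68 and 0.92. With 1 library left out the means ran from −0.64 to −0.19, from −0.63 to −0.15 and from −1.53 to −0.15, each lowest without old control 3. The mitochondrial share of these libraries was 9.03% in old control and 12.4% in young control. With an estimated correlation 1 of the 20 lists that passed (9 higher, 11 lower, of 55) kept its call, complement and MHC. Some calls were lost without 1 library: mature oligodendrocytes and reactive astrocytes without young control 4 (adjusted p = 0.051 for each), the ghrelin and growth hormone axis without young control 4 (0.065), nuclear-encoded oxidative phosphorylation without young control 2 (0.123), anorexigenic neuropeptides without old control 4 (0.159) or young control 2 (0.052), the unfolded protein response without old control 4 (0.147) or young control 2 (0.116). The same held for mitochondrially encoded proteins without old control 1 (0.0523), old control 4 (0.194) or young control 2 (0.162), cytosolic ribosomal proteins without old control 1 (0.182), old control 4 (0.218), young control 2 (0.284) or young control 3 (0.145), and border macrophages and leukocytes without old control 3 (0.0955), old control 4 (0.0882), young control 1 (0.0802) or young control 4 (0.161).

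The count of 6 genes moved with the tool and with single libraries, from 388 by DESeq2 and 3920 by limma-voom to 0 in a fit of the 2 groups alone, and 1663 genes had an unadjusted p under 0.05. It was 0 without old control 2, young control 1 or young control 3, 1 without old control 1, old control 3, old control 4 or any old Gly-Low library, 2 without young control 4 and 6 without young control 2. The highest adjusted p with 1 library left out was that without young control 1, at 0.119 for Mpeg1 and at 0.213 for H2-K1, H2-Q6, Clec7a, Ighm and E230025N22Rik.

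The old diet comparison asks what 5 months of Gly-Low change in old mice. No single gene passed. At the preset correlation 13 lists ranked apart, among them meninges and fibroblasts, higher in old Gly-Low, and oxidative phosphorylation and mature oligodendrocytes, lower, and 0 lists passed with an estimated correlation or by fry. Phldb2, the gene with the smallest p, had 3.74 ± 1.08 CPM in old control (SD, n = 4) and 9.91 ± 0.855 CPM in old Gly-Low (SD, n = 3), a log2 fold change of 1.43 ± 0.27 (SE) with an adjusted p of 0.953. Thbd (1.46 ± 0.30) and the sulfate carrier Slc13a4 (1.76 ± 0.41) followed among higher genes, and the amino acid carrier Slc38a5 (−1.59 ± 0.35), Pllp (−0.87 ± 0.22) and Crybb1 (−1.07 ± 0.31) among lower ones, each with an adjusted p of 0.953. In all, 0 of 18281 genes passed by edgeR, with 433 at an unadjusted p under 0.05, 3 by DESeq2, among them Phldb2 (adjusted p = 0.00421) and Slc38a5 (adjusted p = 0.0407), and 0 by limma-voom. With the replicate number as a block edgeR also called 0, with 3215 at an unadjusted p under 0.05.

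The fixed feeding genes did not pass. Ghsr had 10.3 ± 1.33 CPM in old control and 15.8 ± 1.01 CPM in old Gly-Low (0.64 ± 0.19), Agrp 14.5 and 21.1 CPM (0.58 ± 0.36), and Npy a log2 fold change of 0.70 ± 0.40. The log2 fold change was 1.64 ± 0.93 for Ghrl, 0.63 ± 0.34 for Lepr, −0.25 for Pomc, −0.67 for Cartpt, −1.03 ± 0.51 for Hcrt, −0.39 for Mc4r and −0.25 ± 0.25 for Glo1, and the adjusted p of all these genes was 0.953. Pmch (−0.12, adjusted p = 0.966) and Gfap (0.27 ± 0.64, adjusted p = 0.957) were near 0, and the sign of either turned without old control 3 (0.36 and −0.04).

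The 14 genes of meninges and fibroblasts were all higher in old Gly-Low, 0 of them past the test over all genes and 7 adjusted over the list alone. Their mean was 1.39 (list p = 2.94e-12; adjusted p = 0.4 with an estimated correlation). Slc6a13 was at 5.70 ± 1.23 and 16.2 ± 2.87 CPM (1.53 ± 0.44), Slc6a20a at 1.36 ± 0.44 and Slc22a6 at 1.58 ± 0.54. Of 20 extracellular matrix collagens and laminins none passed by either adjustment, with a mean of 0.92, Col3a1 at 2.26 ± 0.82 and Col1a1 at 1.98 ± 0.73 (list p = 5.89e-05; adjusted p = 0.749 with an estimated correlation); without old Gly-Low 1 the mean was −0.04 (adjusted p = 0.17). Markers of tanycytes, the glia that line the third ventricle, had a mean of 0.53 over 13 genes (list p = 0.00566; adjusted p = 0.746 with an estimated correlation), and 12 choroid plexus markers a mean of 0.41 (list p = 0.0162; adjusted p = 0.4 with an estimated correlation; 0.153 with the replicate number as a block). The 22 genes of leptin and insulin signalling had a mean of 0.30 (list p = 0.0112; adjusted p = 0.807 with an estimated correlation), which was −0.05 with the length slope by merged exon length as a covariate in a fit on all 5 groups, and 19 circadian clock genes a mean of 0.24 (list p = 0.0346; adjusted p = 0.749 with an estimated correlation).

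All 75 genes of nuclear-encoded oxidative phosphorylation were lower in old Gly-Low, with a mean of −0.55, Cyc1 at −0.46 and Ndufs7 at −0.57 (list p = 1.17e-19, and adjusted p = 0.749 with an estimated correlation). The libraries also differed in make-up, as old diet fold changes had a Spearman's rho of 0.46 with transcript length across genes. The mitochondrial share was 6.14% in old Gly-Low and 9.03% in old control (p = 0.343 by the exact permutation test). The 79 cytosolic ribosomal proteins had a mean of −0.48. Rpl17 was at −1.17 ± 0.35 and Rpl30 at −0.94 (list p = 3.88e-12, and adjusted p = 0.807 with an estimated correlation). The list mean was −0.13 with the transcript-length offset, and 0.04 with the length slope as a covariate in a fit on all 5 groups. The 13 mitochondrially encoded proteins had a mean of −1.18. mt-Co2 was at 481 ± 837 and 55.0 ± 8.84 CPM (−3.14 ± 1.31) and mt-Nd3 at −2.40 (list p = 0.0114; adjusted p = 0.837 with an estimated correlation), a mean of 0.08 with that covariate, and −0.08 without old control 3. All 18 markers of mature oligodendrocytes were lower, with a mean of −0.39, Mog at −0.75 ± 0.27 and Gjb1 at −0.53 ± 0.20 (list p = 1.03e-07; adjusted p = 0.4 with an estimated correlation). The 13 anorexigenic neuropeptides had a mean of −0.44. Trh was at −0.94 ± 0.32 and Nts at −1.05 ± 0.42 (list p = 0.00582; adjusted p = 0.749 with an estimated correlation). The 23 genes of methylglyoxal and glycation handling had a mean of −0.16 (list p = 0.0242; adjusted p = 0.807 with an estimated correlation), and 20 glycolysis genes a mean of −0.13 (list p = 0.0348; adjusted p = 0.746 with an estimated correlation; 0.158 with the replicate number as a block). No member of these lists passed by either adjustment.

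In total 13 of 55 lists passed in the old diet comparison, 6 higher and 7 lower. Without old control 3 the mean was −0.22 for nuclear-encoded oxidative phosphorylation and −0.12 for cytosolic ribosomal proteins, and without old Gly-Low 1 that of tanycytes was 0.18. Some calls were lost without 1 library: tanycytes without old control 4 (adjusted p = 0.0706), choroid plexus without old control 4 (0.113) or old Gly-Low 2 (0.098), anorexigenic neuropeptides without old control 3 (0.103), leptin and insulin signalling without old control 3 (0.11) or old Gly-Low 1 (0.161), methylglyoxal and glycation handling without old control 3 (0.118) or old Gly-Low 1 (0.535). The same held for mitochondrially encoded proteins without old control 3 (0.736), old Gly-Low 1 (0.155) or old Gly-Low 2 (0.0502), glycolysis without old control 1 (0.0806), old control 2 (0.0543), old control 4 (0.113) or old Gly-Low 1 (0.388), and circadian clock without old control 2 (0.0744), old control 3 (0.0841), old Gly-Low 1 (0.288) or old Gly-Low 3 (0.139).

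The age genes were then followed into the old diet comparison, which asks whether the diet moves them back. Log2 fold changes of old Gly-Low minus old control were −0.16 ± 0.19 for Mpeg1, −0.39 ± 0.13 for H2-K1, −0.71 for H2-Q6, 0.03 for Clec7a, −0.44 for Ighm and −1.13 for E230025N22Rik, and the smallest unadjusted p, that of H2-K1, was 0.0119. Thus 5 of 6 age genes, or 83.3%, had the opposite sign (exact 95% confidence interval 35.9% to 99.6%). The interval takes the 6 genes as independent, although they were measured in the same libraries. It therefore does not measure the spread between samples. Both contrasts share the old control libraries. Simulations that drew every group, old controls included, from a common mean per gene gave 92.0% on average (66.7% to 100%). They hold no age effect, so they do not give the share for genes that truly differ with age but not with diet. The simulated libraries were independent of each other, so these values leave out any deviation that old control and old Gly-Low libraries of the same number share. Across the 1663 genes with an unadjusted p under 0.05 for age, 60.7% had the opposite sign, against 84.4% in the simulations. The correlation across all genes, which are not independent replicates, was 0.00 with a covariance of 0.0007, against −0.46 and −0.130 in the simulations, a covariance difference of 0.131. With the old controls split 2 and 2, the 6 splits gave 66.7% to 100% of the age genes with the opposite sign and correlations from −0.02 to 0.42. These age genes were called with all old controls, so the splits do not free that share from the shared libraries. Genes with an unadjusted p under 0.05 for age within a split had the opposite sign at 21.5% to 62.6%, with a mean of 42.0%. No overlap of calls could be tested by edgeR, which called 0 genes for the old diet, and DESeq2 called 1 gene in both contrasts.

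The young control and acute control groups differ by 1 month of age and by study arm, and they served to show how far such control groups lie apart. Pituitary hormone genes were higher in acute control than in young control. Prl was at a log2 fold change of 9.07 (adjusted p = 0.0259) and Gh at 8.60 (adjusted p = 0.026), and Pomc rose by 3.57 (adjusted p = 0.024), or 1.96 without acute control 2 (adjusted p = 0.0547). Npy was lower in acute control by −2.87 (adjusted p = 0.0116), Agrp by −1.84 (adjusted p = 0.0116) and Cartpt by −1.11 (adjusted p = 0.0282). Among the acute controls, Gh had 51629 CPM in control 2, 27159 in control 5, 2960 in control 3, 288 in control 4 and 3.28 in control 1. In all, 1009 of 19061 genes differed, 176 higher and 833 lower. The count was 0 without acute controls 2, 3 and 5, 0 without young control 2 or young control 3, 71 without acute control 5, 182 without young control 1, 428 without acute control 1, 510 without acute control 4, 540 without acute control 2 and 3957 without young control 4, by edgeR with 3953 genes at an unadjusted p under 0.05 in the full fit, against 1746 by DESeq2 and 6068 by limma-voom. It was 205 and 411 with the length offset by transcript and merged exon length, and 0 with the length slope as a covariate by either length. Without young control 2 the adjusted p was 0.056 for Npy, 0.0589 for Agrp, 0.0989 for Pomc, 0.116 for Cartpt and 0.106 for Prl and Gh, so each call was lost.

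Set against the young controls, the acute Gly-Low libraries gave a different picture for Agrp. The log2 fold change of acute Gly-Low minus young control was 0.61 for Agrp (adjusted p = 0.154), −2.31 for Npy (adjusted p = 0.000755), −1.22 for Ghsr (adjusted p = 0.00129), −0.84 for Pomc (adjusted p = 0.440), 0.95 for Pmch (adjusted p = 0.0494) and 0.70 for Glo1 (adjusted p = 0.00764). In this contrast 6246 of 19061 genes passed.

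The test of whether the diet effect differed between the old and the acute arm called 6859 of 19061 genes, 3193 with a higher and 3666 with a lower value in the old arm. Among the genes with the smallest p were Arhgap36 (2.56 ± 0.19, adjusted p = 4.8e-07), Adgrf5 (2.65 ± 0.21), Slc1a4 (2.02 ± 0.17) and Med23 (2.04 ± 0.17). Of the fixed genes, the difference of old diet minus acute diet was 1.57 for Ghsr (adjusted p = 0.00263), −1.91 for Agrp (adjusted p = 0.00394), 4.15 for Pomc (adjusted p = 0.00866; 2.53 without acute control 2), −1.85 for Pmch (adjusted p = 0.00966) and −1.15 for Glo1 (adjusted p = 0.00298). With the transcript-length offset 4510 genes passed, with the length slope as a covariate 1374, and without acute controls 2, 3 and 5 the count was 4506. That offset turned the sign of Glo1 (0.09), and the covariate that of Pmch (0.10).

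Across 17038 genes the log2 fold changes of the acute diet and the old diet were inversely related, with Pearson's r of −0.44 and Spearman's rho of −0.53, over genes that are not independent replicates. Of 9970 genes called in the acute comparison and tested in both, 1908 (19.1%) had the same sign in the old diet comparison. The arms shared 0 called genes, since none passed in the old arm. Spearman's rho with transcript length was −0.56 for the acute and 0.46 for the old fold changes. The correlation was 0.11 by limma-voom, −0.06 with 1 surrogate variable, −0.17 without old control 3 and −0.12 without old Gly-Low 1.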

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

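The tests of other splits of the samples, of the length offset, of the length slope covariate for Ghsr and of Agrp against the young controls were chosen only after the results were seen. The tests of the pituitary hormone score and of the length slope inside the other groups were written before their results were seen.

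The count of 10005 acute genes is the first pattern weighed, as the acute Gly-Low libraries also differed in length slope. With the transcript-length offset 8222 genes passed. Of the 10005 acute genes 6321 were among them, and 6063 of these kept their direction. This argues against a length trend as the whole cause only as far as the offset removes that trend. The simulated counts do not show how fully it does so. Random grouping of the libraries alone is argued against, since 1 of 100 splits, the real one, gave as many genes, the smallest share these splits can give. The highest other split gave 8210, so the splits cannot tell the diet from other structure of the libraries. A library quality axis that also varies inside the other 4 groups may contribute, because the change it predicts correlated with the acute change at Spearman's rho of 0.791 over the called genes, which are not independent, and at 0.497, 0.757, 0.624 and 0.778 inside acute control, old control, old Gly-Low and young control. The highest other split set acute controls 2 to 5 against acute control 1 with the Gly-Low libraries. No label gives a batch, and an effect of the diet itself stays open, because diet and library handling are confounded and the diet was not tested apart from them.

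Pomc and Ghsr are the second pattern, as acute controls 2, 3 and 5 held pituitary transcripts, with Prl at 8588, 600 and 4863 CPM and Gh at 51629, 2960 and 27159 CPM. Acute control 1, with Gh at 3.28 CPM, had Pomc at 35.5 CPM, within the 27.1 to 71.0 CPM of acute Gly-Low. Acute control 4, with Gh at 288 CPM, had Pomc at 264 CPM. In the ageing arm, old control 2 and old Gly-Low 1 held Gh at 628 and 1114 CPM. Their Pomc, 131 and 127 CPM, was the highest of their groups. With the pituitary hormone score as a covariate the acute log2 fold change of Pomc was −1.78 (adjusted p = 0.0051), well below the size of its −4.37, so pituitary tissue in the acute controls is a candidate source of much of the Pomc difference, while the part that remained past the threshold is open. With the same covariate Ghsr was −0.92 (adjusted p = 0.0242), near its −0.94, which argues against pituitary tissue as the cause there. In a fit on all 5 groups Ghsr was −0.95 (adjusted p = 0.00386), and with the length slope covariate in that fit it was −0.69 (adjusted p = 0.252; range over the alternatives 8.36e-05 to 0.298). That loss of the call without a loss of most of the value leaves library quality and diet not told apart for Ghsr. A diet effect on either gene stays open and untested.

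Agrp is the third pattern. With the transcript-length offset its log2 fold change was 1.02 (adjusted p = 0.00211), well below the 2.47 without it. The adjusted p ran from 4.77e-21 to 0.032 over the alternatives. A length trend is thus a candidate source of much of the Agrp difference. The part that remained argues against it as the whole cause only as far as the offset removes the trend. The limit for this test was set after the value was seen. Against the young controls, the acute Gly-Low libraries had an Agrp log2 fold change of 0.61 (adjusted p = 0.154), well below the 2.47 against the acute controls, so low Agrp in the acute controls may account for part of the difference. The 2 control groups also differ in age by 1 month, in arm and in library make-up. Length slopes were −0.12, −0.34, −0.17 and 0.30 in young controls 1 to 4, and 0.19 to 0.32 in the acute controls. Log2 fold changes of acute control minus young control had a Spearman's rho of 0.45 with transcript length across genes, which are not independent. This contrast therefore cannot part low Agrp in the acute controls from library make-up. An effect of the diet on Agrp stays open and untested.

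For the other counts, 2 of 35 splits gave as many genes as the 6 for age, so chance cannot be excluded. The highest other gave 4990 genes, many times the real count, and grouped young control 4 with old controls 1, 2 and 4, which points to a structure of the samples. Their length slopes were 0.30, 0.20, 0.06 and 0.17. Those of old control 3 and young controls 1, 2 and 3 were −0.27, −0.12, −0.34 and −0.17, so this split parts the libraries by the sign of the length slope. For the old diet the real value and the highest other were 0, so all 35 of 35 splits gave as many by construction and the test says nothing. For the young groups 2 of 100 splits gave as many as the 1009 genes, and the highest other gave 4811. For the difference between arms 2 of 100 splits gave as many as the 6859 genes, and the highest other gave 9666 genes with old controls 1 and 4 and old Gly-Low 1 in one group. These splits with more genes point to a structure of the samples that the groups do not give, so chance is not excluded for these 2 counts. The splits for the difference also regrouped the acute libraries, so they test any diet effect and not the difference.

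Of 76 groups of values, 4 held a library far from the others, where 3.8 are expected by chance. Pomc was 3161 CPM in acute control 2, above the rest of its group. Glo1 was 192 CPM in acute control 1, above the rest. Ghsr was 9.78 CPM in acute Gly-Low 3, above the other 3 libraries of the group, and 9.97 CPM in young control 1, below the others.

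The test of a different diet effect in the arms called 6859 genes, and 1374 with the length slope as a covariate. Chance is not excluded for this count, and diet and library handling are confounded in the acute arm. The old diet minus acute diet log2 fold change was 2.56 for Arhgap36, 2.65 for Adgrf5, 2.02 for Slc1a4 and 2.04 for Med23. It was 1.57 for Ghsr, −1.91 for Agrp, 4.15 for Pomc, −1.85 for Pmch and −1.15 for Glo1.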

How the results depend on the processing

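The tests with a length offset or the length slope covariate and those without acute controls 2, 3 and 5 or without young control 2 and old control 3 were chosen only after the results were seen. Among values of single genes and lists under settings other than leaving out 1 library, 2423 kept their direction and their side of the threshold, 211 lost a call, 199 gained one and 87 reversed. With 1 library left out, 1570 kept both, 107 lost a call, 1 gained one and 9 reversed. Among main values under other settings, 117 were within the limits, 48 moved and 2 reversed. The 16 genes with the smallest p in the acute comparison kept their direction and their call under all 23 alternatives. In the age comparison the lists of complement and MHC, interferon response, disease-associated microglia, microglia, mural cells and erythrocytes did so under all 24 alternatives of the fit with camera at the preset correlation, and in the old diet comparison meninges and fibroblasts did so under all 22. With an estimated correlation only complement and MHC kept its call for age, and meninges and fibroblasts lost it (adjusted p = 0.4; 0.191 by fry). Simulated libraries of the same depth and number recovered 65.0% of genes with a 4-fold change for age and for the old diet, but 15% and 13% of those with a 2-fold change, so most changes of that size are below what these libraries detect. For each value named below the cause was not tested, and values of lists are means of log2 fold changes that reversed in rank against other genes.

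The count of acute genes, 10005, was 8913 with all 5 groups in one fit, and in that fit 3325 with the length slope covariate by transcript length and 2802 by merged exon length. All values with this covariate, and those with acute control as the young reference, come from the fit of all 5 groups. The count of lists past the threshold, 12, was 22 with no low-count filter, 7 with the length offset by either length, 0 with an estimated correlation and 32 by fry, which tests a list against no change and not against other genes. For age, 6 genes became 388 by DESeq2, 3920 by limma-voom, 11 with no low-count filter, 120 with all 5 groups in one fit (in that fit 70 with acute control as the young reference, and 408 and 406 with the covariate), 0 with only the groups compared (tested by edgeR, 1196 at an unadjusted p under 0.05), 723 with 1 surrogate variable, 35 and 34 with the length offset, and 2 without young control 2 and old control 3. The 20 age lists became 12 with the offset by merged exon length, 1 with an estimated correlation and 10 by fry. For the old diet, 0 genes became 3 by DESeq2, and 13 lists became 6 by limma-voom, 7 and 8 with the offset, 0 with an estimated correlation and 0 by fry. Between the young groups, 1009 genes became 1746 by DESeq2, 6068 by limma-voom, 205 and 411 with the offset, 0 with the covariate by either length and 0 without acute controls 2, 3 and 5. For the difference between arms, 6859 genes became 4510 with the offset by transcript length, 1374 and 1061 with the covariate and 4506 without acute controls 2, 3 and 5. The genes changed in both age and old diet were 0 and became 1 by DESeq2. The 83.3% of age genes with the opposite sign became 100% with upper-quartile factors, without young control 2 and old control 3, and with the age contrast from old controls 1 and 3, 1 and 4, or 3 and 4. It was lower at 57.4% by limma-voom, 64.7% and 68.6% with the offset by merged exon and transcript length, 66.7% without young control 2, 71.1% with 1 surrogate variable, 71.6% by DESeq2 and 71.7% with all 5 groups in one fit. For the acute diet against old diet, the correlation of −0.44 became 0.89 over the 5 age genes tested in both, 0.11 by limma-voom, −0.12 with no low-count filter, −0.061 with 1 surrogate variable, −0.25 with the offset by transcript length, −0.34 with all 5 groups in one fit (in that fit −0.21 with the covariate by either length) and −0.17 without young control 2 and old control 3.

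With the length slope covariate by transcript length, the values that reversed were in the acute diet comparison Ntsr1 0.20, mt-Cytb −0.085, Pfkl 0.12, Ghrl 2.94, Npy −0.67, Cartpt −1.11, leptin and insulin signalling 0.40 and mitochondrially encoded proteins −0.45, in the age comparison cytosolic ribosomal proteins 0.039, in the old diet comparison Pmch 0.44, Gfap −0.28, mitochondrially encoded proteins 0.084 and cytosolic ribosomal proteins 0.040, and in the difference between arms Pmch 0.10. With that covariate by merged exon length they were in the acute diet comparison Ntsr1 0.19, mt-Cytb −0.12, Pfkl 0.13, Ghrl 2.89, Npy −0.73, Cartpt −1.15, leptin and insulin signalling 0.40 and mitochondrially encoded proteins −0.51, in the age comparison cytosolic ribosomal proteins 0.0064, in the old diet comparison Pmch 0.45, Gfap −0.30, leptin and insulin signalling −0.048, mitochondrially encoded proteins 0.10 and cytosolic ribosomal proteins 0.057, and in the difference between arms Pmch 0.17. With the length offset by transcript length they were in the acute diet comparison Npy −1.10, Cartpt −0.85, Lepr 0.16, Glo1 −0.094, leptin and insulin signalling −0.30, nuclear-encoded oxidative phosphorylation 0.39, cytosolic ribosomal proteins 0.83 and erythrocytes 0.58, in the age comparison nuclear-encoded oxidative phosphorylation −0.090 and cytosolic ribosomal proteins −0.029, in the old diet comparison Pomc 0.047, Pmch 0.35, Glo1 0.021, leptin and insulin signalling 0.14, methylglyoxal and glycation handling −0.061, cytosolic ribosomal proteins −0.13 and circadian clock 0.12, and in the difference between arms Glo1 0.092. With the offset by merged exon length they were in the acute diet comparison Npy −1.18, Cartpt −0.84, Lepr 0.097, leptin and insulin signalling −0.45, nuclear-encoded oxidative phosphorylation 0.78 and mitochondrially encoded proteins 0.86, in the old diet comparison Pomc 0.060, Pmch 0.37 and anorexigenic neuropeptides −0.18, and in the difference between arms Pmch 0.15. With limma-voom and quality weights they were in the acute diet comparison Npy −0.17 and Cartpt −0.051, in the age comparison Ghrl 0.58, Mc4r −0.40 and Glo1 −0.085, and in the old diet comparison Pmch 0.47, Mc4r 0.13 and Glo1 0.0060. With 1 surrogate variable they were in the acute diet comparison Hcrt 0.049, in the age comparison cytosolic ribosomal proteins 0.0058, and in the old diet comparison Pmch 0.37. With acute control as the young reference they were in the age comparison Lpl −0.29, Crh 0.17, Oxt 0.084, Ghrh 0.91, Agrp 0.66, Npy 1.41, Pomc −3.14, Cartpt 0.76, Pmch 0.54, orexigenic neuropeptides 0.60, anorexigenic neuropeptides 0.082, neuroendocrine hormones 0.33, nuclear-encoded oxidative phosphorylation 0.60, mitochondrially encoded proteins 0.92, cytosolic ribosomal proteins 0.68 and unfolded protein response 0.035. Without young control 2 and old control 3 they were in the old diet comparison Pmch 0.35 and Gfap −0.060.

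With 1 library left out, the counts ran from 0 to 6 for age, 0 to 3957 between the young groups, 66.7% to 100% for the age genes with the opposite sign and −0.50 to −0.12 for the acute diet against old diet. The single genes that reversed ran, for age, over −0.89 to 0.33 for Ghrl, −0.28 to 0.18 for Mc4r, −0.072 to 0.23 for Glo1 and −0.49 to 0.016 for Lepr, and for the old diet over −0.32 to 0.36 for Pmch and −0.045 to 0.68 for Gfap. With the replicate block the counts were 8583 for the acute diet, 7 for age and 0 for the old diet (3215 at an unadjusted p under 0.05, against 433), Mc4r reversed to −0.046 in the age comparison, and Mc4r (acute diet, adjusted p = 0.086), Ighm (age, 0.058) and E230025N22Rik (age, 0.071) lost their calls, while Trem2 (age, 0.0402) and Ctss (age, 0.0124) passed. The block lost 2 lists for the old diet, glycolysis and choroid plexus, and changed no other call of the old diet that is named. Acute libraries of the same number had correlations of −0.04 to 0.03 and 0 of 4 correlated best with their own number, so these share only a number. For young and old controls the correlations were −0.12 to 0.77, with 2 of 4 best. Their mean was 0.319 for the same number and −0.115 for other numbers. For young control and old Gly-Low these means were 0.216 and −0.068. What libraries of the same number share in the ageing arm was not tested.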

Other observations

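Several fixed gene groups that the text has not yet described did not pass by camera in any of the 3 main comparisons. Of 24 targets of NRF2, the regulator of antioxidant genes, 11 rose and 5 fell in the acute comparison with a mean log2 fold change of 0.50 (adjusted p = 0.118), while 0 passed in the age (adjusted p = 0.974) and old diet (adjusted p = 0.382) comparisons. Of 23 genes of cholesterol biosynthesis, 2 rose and 9 fell in the acute comparison with a mean of −0.42 (adjusted p = 0.16), and 0 passed for age or old diet. Of 13 senescence genes, 3 rose and 1 fell with age adjusted over the list alone and 0 over all genes (adjusted p = 0.0989), and none passed for the old diet (adjusted p = 0.554). Of 19 genes of fatty acid and AMPK targets, 3 rose and 13 fell in the acute comparison with a mean of −0.55 (adjusted p = 0.0859). Of 34 genes of NAD, B vitamin and lipoate metabolism, 11 rose and 10 fell in the acute comparison (adjusted p = 0.774), and 15 astrocyte markers had a mean of 0.33 with age (adjusted p = 0.0787).

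Old Gly-Low set against young control gave 1 gene of 18281, Mpeg1, at 91.2 CPM in old Gly-Low and 29.1 CPM in young control with a log2 fold change of 1.65 (adjusted p = 0.0413). In the same contrast Lpl, a lipase of disease-associated microglia, had a log2 fold change of 2.20 (adjusted p = 0.0779) and Clec7a one of 4.69 (adjusted p = 0.0779), and neither passed.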
